A study of Escherichia coli with 12 samples.

How the data were processed

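RNA had been enriched for mRNA and hybridised to Affymetrix E. coli sense genome arrays, 1 array per sample and 12 in all, per the labels' protocols. Overnight cultures had been diluted 1000-fold in LB and grown to log phase before the incubation in salts, per the labels. The deposited values are linear intensities per probe set, 1 column per array. RMA (version 0.1) is named in the submitters' processing notes; which arrays were processed together and what scaling followed are not given in the sources used here. The values span 7312 probe sets, and the arrays are not equal in distribution, so that a full quantile normalization over these 12 arrays is not what the table holds. Array build and probe positions are not given in the sources used here, so no coordinates are given.

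Genes were named by the locus tag in the probe set identifier, matched to the current symbols of the E. coli K-12 assembly ASM584v2, which was used only for names and gene order. A probe set was left unnamed where GEO's platform annotation gave several symbols or another gene; that annotation gave 1 gene symbol for 4203 probe sets, several for 13 and none for 3096. In all, 4181 probe sets named exactly 1 gene and were tested, each for a different gene; 119 of them carry an identifier that marks probes shared with other sequences. The 2886 intergenic probe sets, 59 phage, plasmid and foreign probe sets, 22 array controls and 164 others without a single current name were left out of the tests of genes.

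Intensities were converted to log2 with no pseudocount and no further normalization. mutS replicates 1 and 3 were averaged on the log2 scale, which leaves 11 samples. A linear model with the 4 genotypes as groups and no covariate was fitted with limma (version 3.58.1) in R (version 4.3.3), with empirical Bayes moderation (7 residual and 4.15 prior degrees of freedom), so that all groups share one estimate of the spread. There were 6 contrasts and 1 test for any difference. p-values were adjusted by Benjamini-Hochberg over the 4181 genes, with a threshold of 0.05. Fold changes are ratios of geometric means of intensity, and SE is the moderated standard error of the log2 difference. Dim genes lie near the level of the foreign probe sets, so their fold changes may understate the change in transcript.

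Before the data were examined, 36 gene lists were fixed from general knowledge of E. coli, with 822 genes, of which 794 were measured; 35 lists had at least 5 measured genes and were tested. Each was tested in the 6 contrasts with camera, with a preset correlation between genes of 0.01, and p-values were adjusted over the 210 tests. camera compares the genes of a list with all other genes. Members were also counted after an adjustment over the list alone. With the preset correlation 50 tests passed. With an estimated correlation 0 passed (lowest adjusted p = 0.981), and with fry, which asks whether the genes of a list move one way on balance, 0 passed. The correlation between ribosomal protein genes was estimated at 0.796.

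The rule for naming genes was also fixed before the data were examined. It takes the 10 largest increases and the 10 largest decreases per contrast among genes that pass with groups that do not overlap (there were 0), dam and mutS in every sample, every measured member of the dam operon, and per described list up to 4 members with the smallest adjusted p and up to 4 that did not pass with the largest log2 difference. Genes named outside this rule are marked as chosen after their values were seen.

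Single values were compared between the 6 samples without Dam and the 5 with Dam by exact permutation over all 462 splits, two-sided. With 3 samples against 3, an exact test cannot give a p under 0.1, so no such test is given for single comparisons.

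The limma step was tested on simulated data with the design of dam against wildtype and 4181 genes, 200 of them changed. It recovered 39 of 67 genes (58.2%) changed by log2 1, 60 of 67 (89.6%) by log2 2 and 65 of 66 (98.5%) by log2 3, with 5 false calls, and it called 0 genes in the simulated mutS against wildtype, which held no change. The changed genes were drawn at random from all genes, and the noise was independent between genes. In the real data the median SE was 0.24 over all genes and 0.61 over the ribosomal protein genes. These recovery shares therefore do not apply to genes that vary that much. In 100 simulations of dam against wildtype without change, in which the ribosomal protein genes were given their estimated correlation, camera with the preset correlation called that list in 75 at an unadjusted p of 0.05 and with the estimated correlation in 6. The preset calls are thus too frequent for lists whose genes vary together.

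Alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 25% of genes, testing all probe sets, eBayes with trend and robust, array weights, the replicate number as a block, fitting only the groups of a contrast, fold thresholds of 1.5 and 2, an estimated correlation, fry and leaving out each array in turn. Added after the data were seen were averaging mutS replicates 1 and 3 in the main fit, leaving both out, a covariate from the control and foreign probe sets, the mean of the 23S and 16S rRNA probe sets as a covariate for the ribosomal list, the additive model, the permutation tests, and random lists matched on intensity. Keeping mutS replicates 1 and 3 apart, as first planned, was then run as an alternative. Figures were drawn with matplotlib (version 3.10.9).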

Results

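Transcript levels were measured on Affymetrix sense-strand genome arrays in Escherichia coli K-12 strain AB1157 and in derivatives labelled as mutated in dam, mutS or both. Dam is the methyltransferase that marks the adenine of GATC sites, and MutS is the protein that recognises mismatched bases and starts mismatch repair. Each of the 4 genotypes (wildtype, dam, mutS and dam mutS) was represented by 3 arrays. The cultures had spent 120 min in M9 salts at 37 °C and 90 min of recovery in LB, as the untreated arm of a study of a chemical, per the labels. For the dam genotype, the label of replicate 1 gives an allele name (an insertion in dam) and the labels of the other two give a strain code. They were treated as one genotype, as their titles say. Over all probe sets the log2 values of dam replicate 1 differed from wildtype replicate 1 with an SD of 0.342. Its SDs from dam replicates 2 and 3 were 0.495 and 0.629, and these differed from each other with 0.522. Whether the unlike labels bear on this was not tested. Nothing in the labels says that replicates came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical.

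The median intensity per array lay between 38.6 and 42.4. As a background, 59 probe sets for phage, plasmid and other foreign sequences gave a 95th percentile of 59.9 to 112 per array, and between 9.06% and 35.3% of the gene probe sets lay above it. The lowest shares were those of wildtype replicates 2 and 3 (9.06% and 9.998%), while wildtype replicate 1 lay at 29.2%. The arrays labelled dam or dam mutS lay between 18.8% and 35.3%, and those labelled mutS between 17.1% and 20.9%. Whether these unequal shares bear on the differences from wildtype was not tested. The Rac prophage and gpt-proA lists, taken as absent from AB1157 when the lists were fixed, were to serve as another background. Their mean log2 minus the array median still varied between samples of a genotype. For Rac the SD ran from 0.11 in dam mutS to 0.44 in mutS, and for gpt-proA from 0.11 in wildtype to 0.44 in mutS. The number of arrays limits the precision of every value below. The spread of log2 intensity over genes was wider on the arrays without Dam (SD 1.12 to 1.38) than on the arrays with Dam (SD 1.04 to 1.20), with ranges that overlap.

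mutS replicates 1 and 3 were nearly the same array. Over 540 bright probe sets (of any kind, mean log2 above 7) their log2 values differed with an SD of 0.112, which is 1.13 times the SD on the foreign probe sets. In every other pair of arrays the SD over the bright probe sets was between 0.478 and 1.37, or 1.49 to 5.16 times that of the foreign probe sets. These replicates differed by slightly more than the noise of the background and far less than any other pair, so they were averaged and counted as 1 sample, which leaves n = 2 for mutS, n = 3 for the other genotypes and 11 samples in all.

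**Figure D1:**
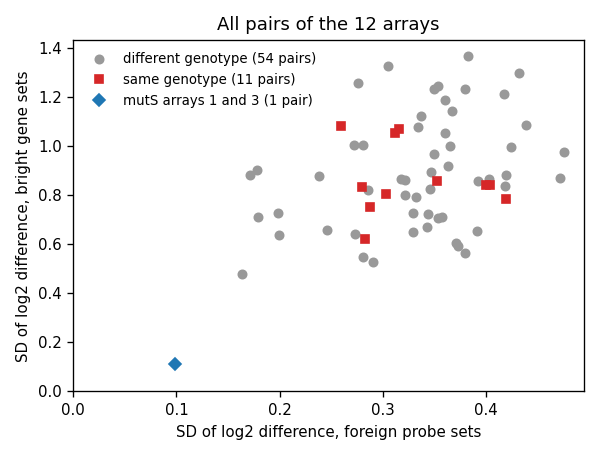
Spread of the log2 difference between each pair of the 12 arrays, over 540 bright probe sets of any kind (y axis) and over 59 foreign probe sets (x axis). Each point is 1 pair; mutS replicates 1 and 3 sit at 0.112 and 0.0989, below every other pair.

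The transcripts of the mutated genes gave little check of the labels. The dam probe set read between 27.1 and 43.7 on all 12 arrays, below the 95th percentile of the foreign probe sets on each of them, so that neither a presence nor a loss of the dam transcript was measurable. The mutS probe set read 69.5, 76.2 and 84.6 in wildtype. On the arrays labelled dam it read 82.8, 93.2 and 111. On the arrays labelled mutS it read 130, 79.6 and 115, and on those labelled dam mutS it read 97.1, 82.5 and 114. It was thus not lower where the label says that mutS is mutated (mutS against wildtype, log2 0.37, limma adjusted p = 0.991). The labels give neither the mutS allele nor the position of the probes, and a transcript can persist in an insertion mutant. The groups are therefore called samples labelled mutS and samples labelled dam mutS throughout. Below, samples without Dam are those labelled dam or dam mutS, and samples with Dam are those labelled wildtype or mutS.

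The first comparison concerns the dam label in the background without the mutS label (dam against wildtype, n = 3 and 3). recA, which encodes the recombinase that starts the SOS response to DNA damage, had a geometric mean intensity of 538 in dam and 137 in wildtype. The difference was log2 1.98 ± 0.33 (SE), or 3.94-fold. lexA, the repressor of the SOS genes, was 2.97-fold higher (log2 1.57 ± 0.41 SE) and yebG, a small SOS gene, 2.91-fold higher (log2 1.54 ± 0.34 SE). sulA, the SOS inhibitor of cell division, was 1.87-fold higher. The wildtype means of lexA, yebG and sulA were 73.2, 66.9 and 53.4, near the background of the foreign probe sets, so that these folds are less certain than that of recA. Of the 33 measured members of the SOS (LexA) regulon, recA, yebG and lexA passed limma when adjusted over the list alone, and 0 passed over all genes tested. The list as a whole did not stand apart from other genes (median log2 0.07, 18 of 33 positive, camera adjusted p = 0.393). After quantile normalization the recA difference was log2 0.93.

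Genes of protein synthesis had the largest group difference in dam against wildtype. All 54 measured ribosomal protein genes were higher in dam, with a median log2 of 2.02, and 51 of them passed when adjusted over the list alone, against 0 over all genes tested. rpsA was 3.04-fold higher, rpsD 4.65-fold, rpsM 4.10-fold and rpmC 3.85-fold. camera with its preset correlation gave adjusted p = 2.95e-32 for the list, and adjusted p = 0.981 with an estimated correlation. The mean log2 of the list above the array median was 3.02 ± 0.70 (SD, n = 3) in dam and 1.08 ± 0.50 (SD, n = 3) in wildtype. Among the 418 brightest genes, the 371 outside this list had a median log2 of 0.61 in the same comparison. After quantile normalization the median of the ribosomal list was 1.30. For ribosomal RNA the differences were negative: the 10 probe sets for 23S and 16S rRNA, all with probes shared with other sequences, lay between log2 -2.15 and -0.42 in dam against wildtype, and 0 passed limma. The probe sets for 5S rRNA lay closer to no difference, between log2 -0.36 and -0.073. Over the 11 samples the mean of the 23S and 16S probe sets correlated with that of the ribosomal protein list (r = -0.722, permutation p = 0.00809; rho = -0.664, permutation p = 0.0301; 1 relation computed, after the data were seen). Without dam replicates 2 and 3 the correlation was -0.621, and within genotypes -0.513 (exact permutation p = 0.273). With the rRNA mean as a covariate, also added after the data were seen, the median of the ribosomal list was 0.99.

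In dam, camera also called 4 lists of sugar uptake and energy metabolism higher, each with adjusted p = 0.981 with an estimated correlation. The TCA cycle (13 of 19 positive, adjusted p = 0.249) and iron uptake (17 of 35 positive, adjusted p = 0.870) were not called. In the list for maltose, galactose, ribose and sialic acid uptake, 25 of 30 members were positive (median log2 0.62, camera adjusted p = 5.85e-08), and 11 passed when adjusted over the list alone, against 0 over all genes. lamB, the maltoporin, was 6.94-fold higher, malE, the periplasmic maltose-binding protein, 5.79-fold, malK 4.89-fold, galT 2.74-fold and malG 2.01-fold. All 27 genes of aerobic respiration and ATP synthase were positive (median log2 0.77, camera adjusted p = 2.73e-08). 7 of them passed adjusted over the list alone, against 0 over all genes, among them the ATP synthase genes atpF (2.56-fold), atpE (2.78-fold), atpH (2.34-fold) and atpA (2.72-fold). The median of this list was 0.42 without dam replicate 3 and 1.19 without dam replicate 1. All 17 glycolysis genes were positive (median log2 1.05, camera adjusted p = 2.22e-07), with fbaA at 2.63-fold, pgk at 2.61-fold and pfkA at 2.36-fold, and 0 passed adjusted over the list alone. In anaerobic respiration and fermentation, 33 of 42 genes were positive (median log2 0.49, camera adjusted p = 0.000279). Of these, glpB (1.67-fold) and glpC (2.09-fold), subunits of the anaerobic glycerol-3-phosphate dehydrogenase, passed adjusted over the list alone, against 0 over all genes, and frdB, a fumarate reductase subunit, was at log2 1.45. The median of the anaerobic list was 0.28 without dam replicate 2.

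Surface structures went in both directions in dam against wildtype. In flagella and chemotaxis, 44 of 52 genes were positive (median log2 0.55, camera adjusted p = 1.35e-07, adjusted p = 0.981 with an estimated correlation), with fliL at log2 1.23, fliG at 1.12 and the flagellin gene fliC at 1.67. In the list of fimbriae, antigen 43 and curli, 16 of 17 genes were negative (median log2 -0.39, camera adjusted p = 0.000144), led by the type 1 fimbriae genes fimE (log2 -0.75), fimH (-0.69) and fimG (-0.50). That list too had adjusted p = 0.981 with an estimated correlation. Only 1 of these 17 genes had a mean above the foreign 95th percentile. Of the 59 foreign probe sets 42 were lower in dam as well, with a median of log2 -0.096 over all 59. Pooled over the samples without and with Dam, the fimbrial difference against the mean of the foreign probe sets was -0.14 (exact permutation p = 0.335). The colanic acid capsule list was lower by camera, with 15 of 22 genes negative (median log2 -0.19, camera adjusted p = 0.0154, wcaL at -0.74 and cpsG at -0.90), but 0 of the 22 genes lay above that background and the list had adjusted p = 0.981 with an estimated correlation. Cold shock (13 of 14 genes positive, median log2 0.96, camera adjusted p = 0.000358, cspB at 1.99, cspA at 1.67 and hns at 1.29) and heat shock (18 of 22 positive, median log2 0.48, camera adjusted p = 0.00608, grpE at 1.67 and ftsH at 1.37) were higher by camera, each with adjusted p = 0.981 with an estimated correlation. In these 5 lists 0 genes passed adjusted over the list alone. The medians of the capsule, cold shock and heat shock lists lay within the 95% range of 10000 random lists matched on intensity (percentiles 5.64, 97.48 and 96.99), and their calls were lost after quantile normalization (medians -0.095, 0.39 and 0.042). Those of the capsule and heat shock lists were also lost without wildtype replicate 3 (medians -0.16 and 0.43), and that of the capsule without the dimmest genes (-0.019); without dam replicate 3 the capsule median was -0.10. The 7 members of the dam operon lay between log2 -0.32 (dam) and 0.51 (aroK), with damX at 0.11, aroB at -0.07, rpe at -0.09, trpS at -0.19 and gph at -0.21, and 0 passed limma adjusted over the list alone. Of these 7 genes 1 had a mean above the foreign 95th percentile.

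In the test over all 4181 genes, limma called 0 genes in dam against wildtype at adjusted p under 0.05 (lowest adjusted p = 0.270). At unadjusted p under 0.05 there were 561 genes, 335 higher (59.7%) and 226 lower in dam, where chance gives 209; after quantile normalization 46.2% of 567 were higher. The values of the groups did not overlap for 20.5% of the genes, where chance gives 10%. With array weights limma called 326 genes, 257 higher and 69 lower, and without dam replicate 1 it called 3. The 69 included 7 rRNA genes, chosen after their values were seen, at log2 -2.64 to -1.82, where the lowest other call was -1.18.

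**Figure D2:**
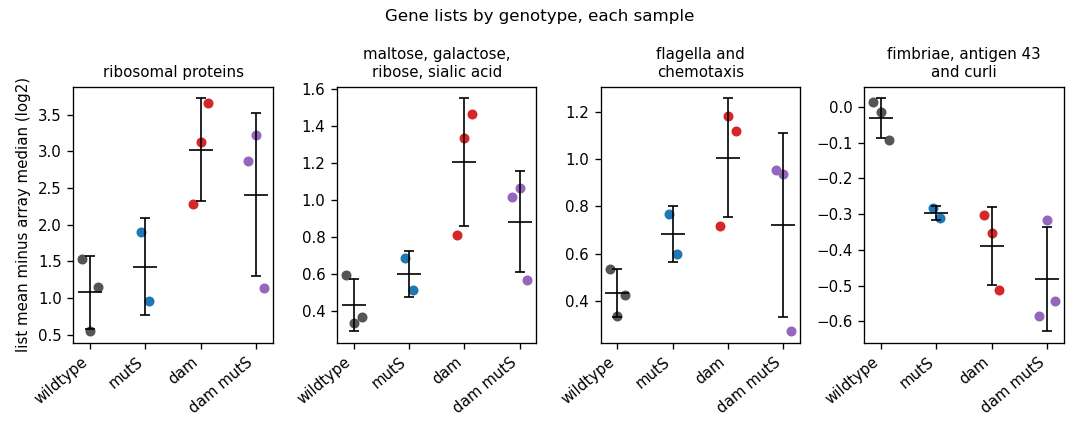
Mean log2 of 4 gene lists minus the median of all genes on the same array (y axis), by genotype (x axis). Points are samples, horizontal marks are means and bars are SDs (n = 3, and n = 2 for mutS); the ribosomal mean is 3.02 in dam, 2.41 in dam mutS, 1.42 in mutS and 1.08 in wildtype.

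The next comparison sets the samples labelled mutS against wildtype (n = 2 and 3). Acid resistance genes were higher in the samples labelled mutS by camera, with 11 of 16 positive (median log2 0.53, camera adjusted p = 0.00466, adjusted p = 0.981 with an estimated correlation). Of the 16, 2 lay above the foreign 95th percentile. The foreign probe sets moved the same way, with a median log2 of 0.18 and only 12 of 59 lower. gadB, a glutamate decarboxylase, was 2.26-fold higher (log2 1.17 ± 0.25 SE) and was the 1 gene of this list to pass when adjusted over the list alone, against 0 over all genes. gadC, the partner antiporter, was at log2 0.91, and the periplasmic acid chaperone genes hdeA and hdeB at 1.67 and 1.27. In flagella and chemotaxis, 50 of 52 genes were positive (median log2 0.40, camera adjusted p = 8.17e-06, adjusted p = 0.981 with an estimated correlation), with cheW at log2 0.79 and fliC at 1.56, and 0 passed adjusted over the list alone. The median of the flagellar list was 0.62 without mutS replicate 2 and 0.17 without the averaged mutS replicates 1 and 3.

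The general stress (RpoS) regulon (24 of 27 positive, median log2 0.34, dps at 1.24), glycolysis (16 of 17 positive, median log2 0.50, fbaB at 0.54 and fbaA at 0.96) and ribosomal proteins (50 of 54 positive, median log2 0.47, rplR at 1.04) were also higher by camera in the samples labelled mutS. Their adjusted p were 0.00885, 0.0122 and 0.0291, and each had adjusted p = 0.981 with an estimated correlation. The lists lower than other genes by camera were fimbriae, antigen 43 and curli (adjusted p = 0.000947, median log2 -0.092, fimH at -0.49 and fimE at -0.45), methionine and cysteine synthesis (adjusted p = 0.00553, median log2 -0.075, with cysE at 0.74) and mismatch repair and DNA methylation (adjusted p = 0.0482, median log2 -0.16, mutL at -0.38 and uvrD at -0.40), each with adjusted p = 0.981 with an estimated correlation. Of their genes, 1 of 17, 2 of 27 and 1 of 8 lay above the foreign 95th percentile. The mismatch repair list was called in 9 of 23 settings (adjusted p = 0.0677 after quantile normalization), and the fimbrial median lay within the range of matched random lists (percentile 6.69). The median of all genes was itself log2 0.13 in this comparison, and re-centring the arrays on their medians turned it to -0.027. 0 genes of these 6 lists passed adjusted over the list alone.

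Over all genes limma called 0 in mutS against wildtype (lowest adjusted p = 0.991), and 52 were at unadjusted p under 0.05, 43 of them higher (82.7%), where chance gives 209. The groups did not overlap for 15.5% of the genes, where chance gives 20%. The share higher was 42.9% after quantile normalization and 12.9% after centring on array medians. Only the flagellar list kept its camera call in every setting other than the estimated correlation and fry. Without mutS replicate 2 the acid resistance, general stress, glycolysis and fimbrial lists lost their calls (medians 0.31, 0.12, 0.71 and -0.20), and the ribosomal median was 1.11. Without the averaged mutS replicates 1 and 3 the ribosomal, glycolysis, methionine and cysteine, and mismatch repair lists lost theirs (medians -0.000730, 0.21, 0.034 and -0.026). Without wildtype replicate 2 the ribosomal, glycolysis and general stress lists did (0.21, 0.26 and 0.25), and without wildtype replicate 3 the acid resistance, general stress and mismatch repair lists (0.48, 0.30 and -0.17).

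dam mutS against wildtype (n = 3 and 3) sets the samples labelled dam mutS against the common reference. recA was 3.07-fold higher in the samples labelled dam mutS (log2 1.62 ± 0.33 SE, geometric mean intensity 420 against 137) and was the 1 SOS gene that passed when adjusted over the list alone, against 0 over all genes. recN, a recombination gene, was at log2 0.83, yebG at 1.03 and lexA at 0.80, and the SOS list as a whole was not called (median log2 0.095, or -0.044 after quantile normalization, camera adjusted p = 0.518). All 54 ribosomal protein genes were positive (median log2 1.37, camera adjusted p = 2.7e-15, adjusted p = 0.981 with an estimated correlation), with rpsD at 3.64-fold and rpsA at 2.30-fold. 16 of 17 glycolysis genes were positive (median log2 0.82, camera adjusted p = 0.000429, adjusted p = 0.981 with an estimated correlation). fbaB, a fructose-bisphosphate aldolase, was 2.10-fold higher (log2 1.07 ± 0.18 SE) and passed adjusted over the list alone, against 0 over all genes, while gpmA was at log2 1.01. 16 of 17 genes of fimbriae, antigen 43 and curli were negative (median log2 -0.45, camera adjusted p = 4e-05), with fimG at log2 -0.60, fimE at -0.77 and fimA, the major fimbrial subunit, at -1.18. The fimbrial list had adjusted p = 0.981 with an estimated correlation and, as above, a pooled difference of -0.14 against the foreign probe sets (exact permutation p = 0.335). These 3 lists kept their camera calls in all alternatives except the estimated correlation and fry, and the ribosomal median was 2.13 without dam mutS replicate 3, the glycolysis median 0.44 without dam mutS replicate 1, and the fimbriae median -0.27 without wildtype replicate 2.

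The other 6 lists called in dam mutS against wildtype lost the call under at least 1 other setting, and each had adjusted p = 0.981 with an estimated correlation. Sugar uptake (26 of 30 positive, median log2 0.38, adjusted p = 0.00257, malG at 0.89, malE at 1.95 and lamB at 2.02), aerobic respiration and ATP synthase (26 of 27 positive, median log2 0.51, adjusted p = 0.0136, nuoK at 0.96) and flagella and chemotaxis (37 of 52 positive, median log2 0.29, adjusted p = 0.0467, fliL at 0.95) were higher by camera, with adjusted p = 0.981 with an estimated correlation for each. Methionine and cysteine synthesis (8 of 27 positive, median log2 -0.18, adjusted p = 0.0237, metR at -0.78), ribonucleotide reductase (2 of 10 positive, median log2 -0.28, adjusted p = 0.0261, nrdB at -0.42) and replication initiation and replisome (8 of 24 positive, median log2 -0.18, adjusted p = 0.0342, dnaC at -0.72 and polA at -0.63) were lower by camera, again with adjusted p = 0.981 with an estimated correlation for each. Of their genes, 2 of 27, 0 of 10 and 2 of 24 lay above the foreign 95th percentile. Of the 59 foreign probe sets 40 were lower as well, with a median of log2 -0.15 over all 59. After quantile normalization the medians of the sugar uptake, respiratory and flagellar lists were 0.18, 0.26 and 0.092, and none of these was called. The methionine and cysteine and the ribonucleotide reductase lists lost their calls too (medians -0.19 and -0.20, adjusted p = 0.0914 and 0.110), and the replication list kept its call (adjusted p = 0.0282). Without dam mutS replicate 2 the respiratory, flagellar, replication and ribonucleotide reductase lists lost their calls (medians 0.32, 0.38, -0.075 and -0.18), and without dam mutS replicate 1 the methionine and cysteine list and the flagellar list did (-0.20 and 0.14). 0 genes of these 6 lists passed adjusted over the list alone. The flagellar, sugar uptake and ribonucleotide reductase medians lay within the 95% range of matched random lists (percentiles 80.9, 93.9 and 2.82). Over all genes limma called 0 (lowest adjusted p = 0.223), and 597 were at unadjusted p under 0.05, 363 higher (60.8%) and 234 lower, with 47.4% higher after quantile normalization. The groups did not overlap for 1004 genes of 4181, where chance gives 10%. With array weights limma called 2 genes.

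dam mutS against dam (n = 3 and 3) asks what the mutS label adds in the dam background. All 54 ribosomal protein genes were lower in the samples labelled dam mutS (median log2 -0.54, camera adjusted p = 3.87e-09, adjusted p = 0.981 with an estimated correlation, rpsR at -0.83), but the median was 0.11 without dam mutS replicate 3, with no call. In aerobic respiration and ATP synthase 25 of 27 genes were negative (median log2 -0.22, camera adjusted p = 3.38e-05, atpG at -0.97 and atpF at -0.80). In flagella and chemotaxis 46 of 52 were negative (median log2 -0.25, camera adjusted p = 1.67e-05, cheW at -0.42). Both lists had adjusted p = 0.981 with an estimated correlation. The remaining lists called lower were cold shock (median log2 -0.42, adjusted p = 0.000584, nusA at -0.76 and cspB at -0.98), anaerobic respiration and fermentation (median log2 -0.27, adjusted p = 0.000674, narH at -0.84 and frdB at -1.20), sugar uptake (median log2 -0.25, adjusted p = 0.000947, malP at -0.90), heat shock (median log2 -0.33, adjusted p = 0.00832, hslV at -0.58), methionine and cysteine synthesis (median log2 -0.089, adjusted p = 0.0252, cysK at -0.66, 2 of 27 genes above the foreign 95th percentile) and sigma E and Cpx envelope stress (median log2 -0.11, adjusted p = 0.0483, dsbA at -0.62). Each of these had adjusted p = 0.981 with an estimated correlation, and none of the 9 lists kept its call in every alternative. Over the arrays left out in turn the ribosomal median lay between -1.04 (without dam replicate 1) and 0.11, the respiratory one between -0.62 (without dam replicate 1) and 0.036, and the sugar uptake call was lost without dam replicate 3 (-0.20). Without dam mutS replicate 3 the medians of the flagellar, respiratory, anaerobic, cold shock and heat shock lists were -0.021, 0.036, -0.022, -0.14 and -0.0013. In the 9 lists 0 genes passed adjusted over the list alone. The cold shock and envelope stress medians lay within the range of matched random lists (percentiles 4.72 and 6.79). recA and the other SOS genes did not pass, with lexA at log2 -0.77. Over all genes limma called 0 (lowest adjusted p = 0.990), and 125 were at unadjusted p under 0.05, 72.8% of them higher, where chance gives 209. The groups did not overlap for 7.10% of the genes, where chance gives 10%. The share higher was 52.0% after quantile normalization and 45.6% after centring on array medians.

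dam mutS against mutS (n = 3 and 2) concerns the dam label in the background labelled mutS. All 54 ribosomal protein genes were positive (median log2 0.87, camera adjusted p = 1.88e-19, adjusted p = 0.981 with an estimated correlation, rpmF at 1.18 and rplA at 1.49), and the median was 0.34 without mutS replicate 2 and 1.52 without dam mutS replicate 3. recA was 2.64-fold higher (log2 1.40 ± 0.37 SE) and yebG 1.96-fold (log2 0.97 ± 0.38 SE), and 0 SOS genes passed adjusted over the list alone. For the SOS list the mean was log2 0.097 and the median -0.0035, of opposite sign, and camera did not call it (adjusted p = 0.249). All 17 genes of fimbriae, antigen 43 and curli were negative (median log2 -0.21, camera adjusted p = 0.00943, adjusted p = 0.981 with an estimated correlation, fimI at -0.52 and fimA at -1.19). Glycolysis (median log2 0.25, adjusted p = 0.0112, fbaB at 0.52), aerobic respiration and ATP synthase (median log2 0.24, adjusted p = 0.0154, atpD at 0.84) and sugar uptake (median log2 0.23, adjusted p = 0.019, lamB at 0.87 and malE at 0.78) were higher by camera, and the general stress (RpoS) regulon was lower (median log2 -0.24, adjusted p = 0.0261, glgS at -1.69 and cbpA at -0.73), each with adjusted p = 0.981 with an estimated correlation. After quantile normalization the fimbrial, glycolysis, respiratory and sugar uptake lists were not called (medians -0.13, 0.017, 0.11 and 0.12), and without mutS replicate 2 the general stress median was -0.041, with no call. Without dam mutS replicate 1 the glycolysis, sugar uptake and fimbrial lists lost their calls (medians -0.077, 0.044 and -0.30), and without dam mutS replicate 2 the general stress, respiratory, glycolysis and sugar uptake lists did (-0.096, 0.0086, 0.17 and 0.17). In the 6 lists 0 genes passed adjusted over the list alone. The glycolysis median lay within the range of matched random lists (percentile 81.4). Over all genes limma called 0 (lowest adjusted p = 0.992), and 89 were at unadjusted p under 0.05, 32.6% of them higher, where chance gives 209. The groups did not overlap for 12.7% of the genes, where chance gives 20%. The share higher was 48.7% after quantile normalization and 77.1% after centring on array medians.

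The interaction asks whether the effect of the dam label differed between backgrounds with and without the mutS label. In all 8 lists that camera called, the Dam effect was smaller in the background labelled mutS, but each of the 8 had adjusted p = 0.981 with an estimated correlation. For ribosomal proteins 54 of 54 genes were negative (median log2 -1.12, adjusted p = 1.08e-11, rplX at -1.49 and rplE at -1.95), and for flagella and chemotaxis 51 of 52 (median log2 -0.65, adjusted p = 3.06e-13, cheW at -1.21 and fliC at -2.24), both with adjusted p = 0.981 with an estimated correlation. For sugar uptake 26 of 30 were negative (median log2 -0.50, adjusted p = 1.12e-05, malP at -1.37 and lamB at -1.93), and for anaerobic respiration and fermentation 33 of 42 (median log2 -0.52, adjusted p = 0.000429, glpB at -0.69 and frdB at -1.73), both with adjusted p = 0.981 with an estimated correlation. Aerobic respiration and ATP synthase (26 of 27 negative, median log2 -0.59, adjusted p = 2.09e-05, atpF at -1.18), glycolysis (16 of 17, median log2 -0.61, adjusted p = 0.000414, fbaA at -1.33), heat shock (21 of 22, median log2 -0.52, adjusted p = 0.00201, grpE at -1.24) and cold shock (12 of 14, median log2 -0.69, adjusted p = 0.0158, nusA at -0.92 and cspA at -1.27) were called as well. These 4 lists likewise had adjusted p = 0.981 with an estimated correlation. In the 8 lists 0 genes passed adjusted over the list alone, and without dam mutS replicate 3 the ribosomal median was -0.44 and the flagellar and anaerobic ones -0.41 and -0.29. The glycolysis median lay within the range of matched random lists (percentile 3.44). The heat shock, glycolysis and cold shock lists lost their calls without dam mutS replicate 3 (medians -0.25, -0.23 and -0.27), and the respiratory list without dam replicate 3 (-0.28). The heat shock and cold shock calls were also lost after quantile normalization (medians -0.22 and -0.28, camera adjusted p = 0.0818 and 0.144). The recA interaction was log2 -0.58 ± 0.49 (SE, limma adjusted p = 0.998) and turned to 0.15 after quantile normalization. Over all genes limma called 0 (lowest adjusted p = 0.998), and 34 were at unadjusted p under 0.05, 50% of them higher (59.5% after centring on array medians). The test for any difference between the 4 genotypes likewise called 0 genes (lowest adjusted p = 0.629), with 330 at unadjusted p under 0.05, where chance gives 209.

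**Figure D3:**
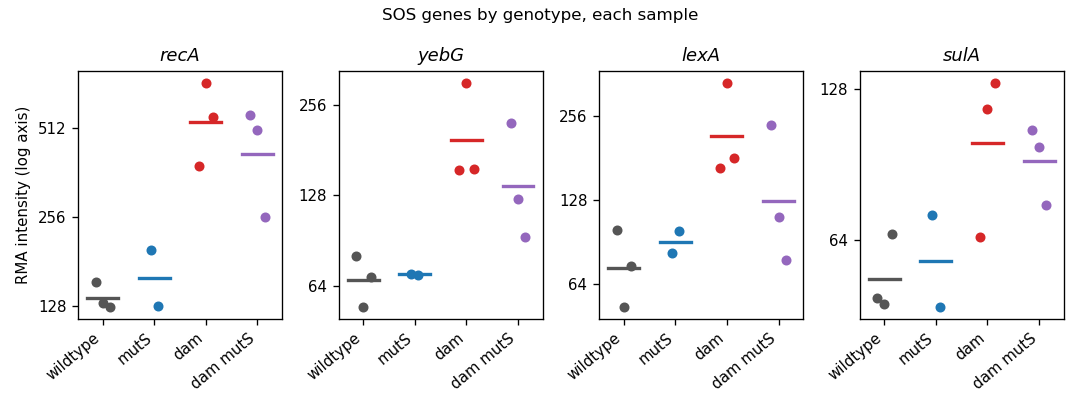
RMA intensity of 4 SOS genes in each sample (y axis, log scale), by genotype (x axis). Points are samples and horizontal lines geometric means (n = 3, and n = 2 for mutS); recA reads 256 to 731 in the samples without Dam and 126 to 198 in those with Dam.

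Because both pairs of genotypes that differ in Dam are in the design, the SOS genes were also compared between the 6 samples without Dam and the 5 samples with Dam, a comparison added after the data were seen. recA was 3.27-fold higher without Dam, 256 to 731 against 126 to 198, and all 6 samples without Dam lay above all 5 with Dam (exact permutation test over 462 splits, two-sided p = 0.00433, adjusted p = 0.0476 over the 33 SOS genes). The smallest p that this test can give is 0.00216. yebG was 2.40-fold higher with the same p, again in 6 of 6 samples. umuC, part of the SOS polymerase and chosen after its values were seen, was lower in 6 of 6 samples (0.740-fold, with the same p). It read 55.1 to 81.2 against 88.8 to 94.3, near the foreign 95th percentile of 59.9 to 112, and the mean of the foreign probe sets above the array median was itself lower by -0.16 without Dam (exact permutation p = 0.0996). recN, also chosen after its values were seen, was 1.60-fold higher (exact permutation p = 0.00866, adjusted p = 0.0714), sulA 1.74-fold higher (exact permutation p = 0.0130, adjusted p = 0.0857) and lexA 2.09-fold higher (exact permutation p = 0.0238, adjusted p = 0.112), with 5 of 6 samples without Dam above all 5 with Dam in each case. Of the 5 samples with Dam, yebG was above the foreign 95th percentile of its sample in 1, lexA in 2, sulA in 0 and recN in 0, so these folds are set against values near background, while recA was above it in all 11. After quantile normalization recA was 1.99-fold and yebG 2.01-fold higher, still with all 6 samples above all 5, whereas umuC was below all 5 in 4 of 6 samples, and in 5 of 6 after centring on array medians (exact permutation p = 0.00866 in both). In limma's additive model of Dam and MutS, 0 genes passed and recA had the lowest adjusted p, 0.0632 (3.30-fold), with 689 genes at unadjusted p under 0.05.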

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

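The tests of ribosomal RNA, growth state, label swaps, shared processing and mutS background were chosen only after the results they bear on were seen, and that of matched lists was added after the data were seen but before its own result was.

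In 8 gene lists the effect of the dam label differed between the backgrounds with and without the mutS label, by the interaction test (camera with a preset correlation). The differences in median log2 were -0.65 for flagella and chemotaxis, -0.52 for heat shock, -0.52 for anaerobic respiration and fermentation, -0.59 for aerobic respiration and ATP synthase, -0.61 for glycolysis, -1.12 for ribosomal proteins, -0.50 for sugar uptake and -0.69 for cold shock. All had adjusted p = 0.981 with an estimated correlation, and the heat shock and cold shock calls were lost after quantile normalization. Of 100 splits of the samples, 65 gave as many shifted lists (8 in the real one, up to 19 in the others), so chance is not excluded.

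The higher ribosomal protein transcripts in dam than in wildtype (median log2 2.02, 54 of 54 genes positive) were set against 3 technical or physiological explanations. For the wider spread of intensities on the arrays without Dam, 10000 random lists were matched on intensity. Their medians were centred on 0.70, with 95% of them between 0.51 and 0.94, and the list lay at percentile 100. The random genes were drawn independently while ribosomal protein genes vary together, so that range is too narrow for a test. Genes of like intensity thus rose less, but the wider spread as the whole cause is not excluded. Ribosomal RNA carried over to different extents between RNA preparations cannot be told apart from an effect on the transcripts: the correlation of the 23S and 16S mean with the list mean within genotypes was -0.513 (exact permutation p = 0.273, n = 11), and with that mean as a covariate the list median was 0.99, with 52 of 54 genes positive. The 5S rRNA probe sets, at log2 -0.36 to -0.073 in dam against wildtype, were not part of that mean. A growth state that differed between cultures regardless of genotype stays open, since the share of the variance of the list mean between genotypes, 61.0%, had a permutation p of 0.0827, and the list mean by Dam status had an exact permutation p of 0.0173 (stratified 0.025) that did not pass over 35 lists (adjusted p = 0.121 and 0.175; 5 of 6 samples above all 5). An effect of the dam genotype stays open as well.

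Samples did not group by genotype, as the nearest sample was of the same genotype for 2 of 11 samples (2.00 under shuffled labels, one-sided permutation p = 0.583). By Dam status the nearest sample differed for dam 1 (nearest to wildtype 1), dam mutS 3 (wildtype 3) and the averaged mutS 1 and 3 (dam mutS 1). For every other sample the nearest one had the same Dam status. Grouping by Dam status was not tested against shuffled labels, so it stays open. recA was above all 5 samples with Dam in 6 of 6 samples without it, which goes against a swap between a sample without Dam and one with Dam. That separation had been seen before this check was chosen, so it is not an independent test of the labels. Sample distances over the control and foreign probe sets correlated with those over genes (r = 0.255, one-sided permutation p = 0.0402). Shared processing of arrays could give such a correlation. The labels give no batch, so no value within batches can be had. Of the other splits of a pair of genotypes, 1 (wildtype 1 beside dam mutS 1 and 2) called 63 genes at adjusted p under 0.05 where the real split called 0, and all others called 0 or 1. It was picked after its count was seen and not tested against chance, so whether the samples have a structure other than genotype stays open.

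The mutS signal was not lower in the samples labelled mutS. If the probe set read only background, the label could not be checked from it, but 8 of 12 arrays had mutS above the 95th percentile of the foreign probe sets, which leaves this open. An allele that leaves the probed part transcribed, and a wrong label, were not tested.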

How the results depend on the processing

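Averaging mutS replicates 1 and 3, leaving both out, the covariate from control and foreign probe sets, the rRNA covariate and the pooled permutation tests were chosen only after the data were seen. Keeping these replicates apart was the design first planned. Dim signal limits these data, with 9.06% to 35.3% of genes above the foreign 95th percentile per array. Where mutS was left with 1 sample, that sample was assumed to vary like the other groups. The mean of all probe sets of a gene was not run, since each gene had 1. Where no cause is given below, the cause was not tested.

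Counts of genes stayed at 0 except with array weights (326 in dam against wildtype, 2 in dam mutS against wildtype; wildtype replicate 2 had weight 3.15, the others down to 0.672) and with arrays left out in turn in dam against wildtype (0 to 3). The lowest adjusted p over all settings in dam against wildtype was 0.0270. Of the list calls, 0 remained in each of the 6 contrasts with an estimated correlation and 0 with fry. Quantile normalization left 4 in dam mutS against wildtype. Without the dimmest genes, which tests fewer genes, 5 were left in mutS against wildtype and 5 in dam mutS against wildtype. Array weights left 3 in dam mutS against mutS, and keeping the mutS arrays apart left 5 in mutS against wildtype. With arrays left out in turn, the calls ranged from 5 to 12 in mutS against wildtype, 5 to 11 in dam mutS against wildtype, 4 to 11 in dam mutS against dam, 3 to 11 in dam mutS against mutS and 6 to 14 in the interaction.

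Leaving out arrays in turn reversed the direction of the camera test for some lists. That direction is relative to all other genes, so the median of a list need not change sign with it. The medians of these lists ranged from 0.12 to 0.48 (general stress) and -0.000730 to 1.11 (ribosomal proteins) in mutS against wildtype, -0.62 to 0.036 (aerobic respiration) and -0.25 to 0.069 (methionine and cysteine) in dam mutS against dam, and -0.52 to -0.041 (general stress) and 0.0086 to 0.53 (aerobic respiration) in dam mutS against mutS.

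Named genes changed sign in dam against wildtype for aroB (0.14 with array weights, -0.22 to 0.14 with arrays left out), damX (-0.029 after quantile normalization, -0.0040 to 0.18) and rpe (0.032 after quantile normalization, -0.26 to 0.013). With arrays left out, uvrD in mutS against wildtype ranged from -0.82 to 0.011, and in dam mutS against mutS lamB ranged from -0.48 to 2.22 and malE from -0.025 to 1.59. The ribosomal median in dam against wildtype was 0.99 with the rRNA covariate. The recA interaction was 0.15 after quantile normalization. The cause was not tested for any of these.

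The replicate numbers did not pair the samples. Of 18 same-number pairs, 8 had a correlation of deviations over 0.1 (range -0.478 to 0.403), and 3 of 12 arrays were closest to their own number. The fit with the replicate block called 0 genes in every comparison, as without it.

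Apart from these, 1080 values of list medians kept direction and call and 230 lost the call, while 2646 values of named genes kept theirs and 30 came to pass the threshold, each with array weights.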

Other observations

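The pooled comparisons of gene lists the lists matched on intensity, the direction of the foreign probe sets and the agreement of the Dam effect were tests chosen only after the data were seen.

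Type 1 fimbriae, antigen 43 and curli genes, which build adhesive surface structures, had a mean log2 lower by -0.30 in the 6 samples without Dam than in the 5 with Dam, and 5 of 6 samples lay below all 5 (exact permutation test over 462 splits, two-sided p = 0.00433, adjusted p = 0.114 over 35 lists). Of these 17 genes 1 lay above the foreign 95th percentile, and against the mean of the foreign probe sets the difference was -0.14 (exact permutation p = 0.335). Purine and pyrimidine synthesis, which makes the bases of nucleotides, was higher by 0.19 (exact permutation p = 0.0173, adjusted p = 0.121, 5 of 6 samples above all 5). The SOS list was higher by 0.19 (exact permutation p = 0.00649, adjusted p = 0.114, 5 of 6), and by 0.14 without recA (exact permutation p = 0.00866). Its members went both ways, with recA at 1.71 and yebG at 1.26 against uvrA at -0.27 and ftsK at -0.20, chosen after their values were seen. The mean thus does not show a shift of the whole regulon. Sugar uptake was higher by 0.54 (exact permutation p = 0.0130), ribosomal proteins 2.83-fold (exact permutation p = 0.0173) and glycolysis by 0.66 (exact permutation p = 0.0281), each in 5 of 6 samples. The mean of 23S and 16S rRNA was lower by -0.77 in the same comparison (exact permutation p = 0.117, 3 of 6 samples below all 5). The adjusted p of sugar uptake, ribosomal proteins and glycolysis were 0.121, 0.121 and 0.164, so 0 of 35 lists passed. With splits within the 2 backgrounds only (200), the stratified permutation p was 0.010 for fimbriae and SOS, 0.020 for sugar uptake, 0.025 for ribosomal proteins and for purine and pyrimidine synthesis (adjusted p = 0.175 for each of these 5), and 0.060 for glycolysis (adjusted p = 0.295). After quantile normalization the SOS difference was 0.045 (exact permutation p = 0.279) and that of glycolysis 0.23 (exact permutation p = 0.156). Sugar uptake fell to 0.30 (exact permutation p = 0.0108) and ribosomal proteins to 1.87-fold (exact permutation p = 0.0238). Purine and pyrimidine synthesis was at 0.13 and fimbriae at -0.29 (exact permutation p = 0.0195 and 0.00433). Leaving out 1 sample at a time kept the unadjusted p under 0.05 in 5 of 11 cases for glycolysis and in 11 of 11 for the other lists named here.

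The log2 effects of the dam label in the 2 backgrounds, which share no sample, correlated over genes (r = 0.623, rho = 0.548; genes are not independent replicates). Of 200 splits within the backgrounds, 16 gave a correlation as large in size, up to 0.812, so chance is not excluded. At unadjusted p under 0.05 in both, there were 39 genes, 38 of them in the same direction, where independent lists give 11.9. At adjusted p under 0.01, 0.05 or 0.1 in both there were 0 genes. Both sets of p come from one fit with the same estimate of spread per gene, so the lists are not independent. Genes of small spread tend to enter both, so 39 against 11.9 does not by itself show a shared effect.

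Of the 50 list calls by camera, 11 had a median within the 95% range of random lists matched on intensity and 39 lay outside it. The random genes were drawn independently, so that range is too narrow for lists whose genes vary together. A median outside it is therefore no evidence of a shift beyond chance.

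A hypothesis was that loss of Dam changes gene dosage near the replication origin, which would give a falling signal with distance from it. The rank correlation with that distance, with the trend with intensity removed, was -0.026 in dam against wildtype (circular-shift permutation p = 0.759). It was -0.12 in dam mutS against mutS (p = 0.287 by the same permutation). In mutS against wildtype, where the Dam label does not differ, it was 0.26 (p = 0.229 by the same permutation), the largest in size. These values neither show nor exclude such a gradient.

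Other splits of the same samples bear on the counts at unadjusted p under 0.05. With 10 splits per pair of groups, no share under 0.05 can be had. As many genes as in the real split were given by 1 split in dam against wildtype (561, highest other 335), 8 in mutS against wildtype (52, highest other 490), 1 in dam mutS against wildtype (597, highest other 465), 8 in dam mutS against dam (125, highest other 550) and 8 in dam mutS against mutS (89, highest other 567). Of 100 splits, 87 gave as many genes for the interaction (34, highest other 1695) and 27 for any difference between genotypes (330, highest other 1483), so chance is not excluded there. As many lists were given by 2 of 10 splits in dam against wildtype (10, highest other 14), 6 in mutS against wildtype (8, highest other 11), 4 in dam mutS against wildtype (9, highest other 15), 7 in dam mutS against dam (9, highest other 12) and 9 in dam mutS against mutS (6, highest other 13).

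Among the 59 foreign probe sets limma called 0 in each comparison against wildtype (lowest adjusted p 0.346, 0.985 and 0.236 for dam, mutS and dam mutS), with 4, 0 and 5 at unadjusted p under 0.05. Of the 59, 42 were lower in dam and 40 in dam mutS than in wildtype, while 12 were lower in mutS. Over all 59 the median log2 was -0.096, -0.15 and 0.18 for dam, dam mutS and mutS. Of the 26 phage lambda probe sets, 22 were lower in dam and 20 in dam mutS (medians -0.30 and -0.23).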
